A study of Mus musculus with 23 samples.

How the data were processed

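Per the labels' protocols, RNA was taken from skeletal muscle with TRIzol and 1 ug of total RNA went into each library, prepared with the SMARTER mRNA-Seq kit. The genome builds were GRCm38 and mm10 per the submitters' processing notes. The aligner, the counting tool, the annotation and the strandedness of the kit are not given in the sources used here. For the first set the authors deposited raw counts per gene for 9 libraries, with no scaling. For the second set the authors deposited log2 values per library, on the variance-stabilised scale of DESeq2, for genes above a low mean. The deposited signal column of that table is the mean over its 8 libraries of counts divided by size factors. The score column is the Wald statistic of the authors' DESeq2 test, the fold change divided by its standard error. The p-value columns hold p and adjusted p of the authors' DESeq2 tests, as deposited, for NRF1 KD and for double KD against WT con. A further deposited table holds the authors' log2 fold changes, p-values and adjusted p for denervated against knockdown muscle and for denervated against innervated muscle. The log2 column of the latter comparison mixes numbers with spreadsheet errors and was not used here.

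Columns were matched to groups from their names and the labels alone, never from values. Column names of the first set carry animal-like numbers that the labels lack, so columns were tied to groups and not to single samples. The libraries of each group are called 1 to 3 here in ascending order of these numbers. The labels list 6 samples without a column, which were not analysed here: WT con library 1, and all of 2 groups, the 2 samples labelled WT Innervated and the 3 denervated WT samples at 14 d. The planned comparisons with muscle at 14 d were therefore not made.

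The values of the second set were inverted to normalised counts. With m the smallest value of the table (6.84), a value v gives (2^v - 2 m)2 / 2^v. The mean over libraries differed from the deposited mean signal by at most 3.34e-07% for all 15624 genes. Size factors that make the values whole were then sought, and 100% of the recovered reads lay within 0.05 of a whole number. The count table held 54446 genes, of which 24397 had 0 counts everywhere, and 15526 genes of the second set were found in it. Symbols and coordinates came from a GENCODE annotation on GRCm38, and 15598 genes of the second set matched a symbol.

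Raw counts were tested in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood F test, TMM scaling, genes kept by filterByExpr and all groups of the set in 1 fit. Normalised counts were tested with limma 3.58.1 (limma-trend) on log2 of the value plus 1, at the authors' size factors. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Each adjusted p in the report is from these models unless another tool is named, and so are log2 fold changes and their standard errors. Means are given with the SD over libraries, in CPM at TMM-scaled library sizes or as normalised counts. Gene lists, 39 in number, were written down before the data were examined, as were the samples used, the tests, the named-gene rule and most alternatives. Lists with 5 or more measured members were tested with camera at a preset inter-gene correlation of 0.01, on the same design, with p adjusted over the lists of a comparison. The proteasome list joins the core, the regulatory particle and the assembly chaperones and was tested alone, so its p is not adjusted. Each list was also tested with a correlation estimated from the residuals and with fry. Members were counted with p adjusted over all genes and with p adjusted over the list alone.

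Genes were named by a rule. Pax4, Nrf1, Psmc2, Vcp, Trim63, Fbxo32 and Nedd4 were given in every comparison. The 5 highest and 5 lowest fold changes were given among called genes with a mean of at least 8 CPM and no overlap between the libraries of the groups, without provisional symbols. A gene that met this rule is not reported here. Per list described, up to 2 members in each direction were given by smallest adjusted p among called genes, or by smallest p where none was called. Other genes are marked in the text as chosen after their values were seen; levels of Chrng, Chrna1, Gadd45a and Cd68 per library were also chosen that way.

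Alternatives for each comparison were at least 5 CPM, only the groups compared, a fold change of at least 1 on the log2 scale, and each library left out. The first set also had DESeq2 size factors, DESeq2 1.42.0, limma-voom and no filter on low counts. The second set also had pseudocounts of 0.1 and 5 and a replicate block. In the first set a block was run for denervation only. Sets of 200 genes by smallest adjusted p were an alternative for the denervation-responsive genes. Libraries were compared within groups by correlation, by chi-square and by principal components.

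The planned analysis was changed in these ways. The contrast of contrasts had been planned for raw counts of both sets and was run on raw counts of the first and recovered reads of the second. The test of denervation-responsive genes in PAX4 KO had been planned with 14 d muscle; sets defined with 1 denervated WT library and tested against the other 2 took its place. At the preset correlation 3 of 3 sets lowered by denervation (p = 5.03e-07, 0.00540 and 3.96e-08) and 2 of 3 raised sets (p = 0.00108 and 0.0475; the other 0.350) were shifted down in PAX4 KO. None passed with an estimated correlation (p = 0.284 to 0.852). Scaling by TMM, the deposited log2 values themselves, and edgeR, DESeq2 and limma-voom on recovered reads were added for the second set once its unit was known. The fit without the 2 doubted libraries, innervated 2 and denervated WT 1, was added after their values were seen.

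The pipeline was tried on simulated counts with the means and dispersions of each set and 200 changed genes, in 5 draws of 16146 or 15567 genes. A fold of 1.5 was found in 14.6% to 33.7% of changed genes, 2 in 66.9% to 80% and 4 in 97.3% to 100%. False genes made up 6.20% to 7.39% of calls, above the nominal 5%. A first version with 1 draw was replaced by 5 draws after its result was seen. Lists of 40 genes shifted by 0.3 were called in 100% of cases at the preset correlation, and unchanged lists in 0.4% to 1.4%; simulated genes were independent of one another, which real genes are not.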

Results

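RNA was sequenced from skeletal muscle of mice whose muscle had been denervated, an operation that cuts the nerve supply and leads to atrophy, and from innervated muscle. The series title places the question with the proteasome, the complex of a 20S core particle and 19S regulatory particles that degrades proteins tagged with ubiquitin, and with the transcription factors that control its genes. The libraries formed 2 sets. The first set held raw read counts per gene for 9 libraries. Innervated WT muscle had 3 (24619026, 42821396 and 35003785 counts for libraries 1 to 3), WT muscle at 10 d after denervation 3 (38347204, 36529572 and 36704419) and denervated muscle labelled PAX4 KO 3 (31223080, 21716216 and 37558199). PAX4 is a paired box transcription factor. The second set held deposited log2 values for muscle at 10 d after denervation, from which reads were recovered. These were 2 WT libraries labelled con 2 and con 3 (25982612 and 28674887 reads), 3 labelled NRF1 KD (27951031, 30165765 and 29399528) and 3 labelled NRF1-PAX4 double KD (23740769, 25380278 and 26331538). The labels name the NRF1 target with the suffix PAL, which points to alpha-PAL, the product of Nrf1 (chromosome 6, 30047988 to 30153458, GRCm38) and an activator of genes for mitochondrial proteins. It is not NFE2L1, which is also called NRF1. The strandedness of the kit is not stated, so reads of antisense transcripts and of close paralogs may be counted under a gene. The labels do not say that each library came from its own animal, so the p-values measure the spread between these libraries, which may be technical in part.

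The targeted genes did not check the labels. Pax4 had 0 counts in all 9 libraries of the first set, which allows up to 0.0701 to 0.138 CPM (counts scaled to library size) per library by the limit of 3 counts, for counting error only. It was not listed in the second set. Nrf1 had a log2 fold change of -0.27 ± 0.15 (SE) with denervation of WT muscle (edgeR, adjusted p = 0.191). In PAX4 KO against WT it was -0.12 ± 0.15 (adjusted p = 0.760). In the second set Nrf1 stood at 488 and 444 normalised counts in the WT con libraries, at 499, 476 and 524 in those labelled NRF1 KD and at 450, 427 and 454 in those labelled double KD. The log2 fold change of Nrf1 was 0.10 ± 0.12 (SE) for NRF1 KD against WT con (adjusted p = 0.618, limma) and -0.07 ± 0.12 for double KD against WT con (adjusted p = 0.784). Nrf1 mRNA was therefore not lower in the libraries labelled NRF1 KD, and groups are named below by their labels only. A loss of protein was not measured. In each group the libraries differed by far more than counting noise (chi-square per degree of freedom of 21.8 to 84.4), so none was counted as a repeat of another.

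Denervation of WT muscle came with higher expression of the proteasome. Of 41 measured genes of the 20S core, the 19S particle and the assembly chaperones, 28 rose and 13 did not pass the test, with a median log2 fold change of 0.50 and a range of 0.00 for Psmd9 to 1.15 for Psmg4. In edgeR's test 0 fell; 31 had an unadjusted p under 0.05, and 31 rose when adjusted over the list alone. Psmd11, a subunit of the 19S lid, rose to 194 ± 8.40 CPM, a log2 fold change of 0.98 (SD, n = 3, adjusted p = 0.000325). The ubiquitin receptor Psmd4 rose from 126 ± 8.94 to 255 ± 44.2 CPM (adjusted p = 0.000952). The core subunits Psmb1 and Psma4 rose 1.69-fold and 1.57-fold, and the assembly factor Pomp 1.76-fold. Psmc2, an ATPase of the 19S base (chromosome 5, 21785283 to 21803787, GRCm38), rose from 138 ± 8.32 to 200 ± 19.6 CPM (log2 fold change 0.51 ± 0.11, adjusted p = 0.00628). By part, 10 of 14 core, 14 of 19 regulatory and 4 of 8 assembly genes rose. The set test with a preset correlation (camera) gave p = 4.97e-11 for the 41 genes, and p = 0.149 with an estimated correlation.

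Other genes of protein breakdown moved less evenly. The ATPase p97 extracts ubiquitinated proteins. Of p97 and its cofactors, 6 of 13 rose and 0 fell (7 and 0 adjusted over the list alone), among them Ubxn4 (2.57-fold) and Derl1 (1.67-fold). Vcp, which encodes p97 itself, had a log2 fold change of 0.11 ± 0.12 (adjusted p = 0.484). The list had an adjusted p of 0.00251, and an adjusted p = 0.423 with an estimated correlation. Of 16 ubiquitin ligases and ubiquitin genes of muscle atrophy, Fbxo30 and Mdm2 rose, Ube2b fell and 13 did not pass (1 rose and 0 fell adjusted over the list alone; list adjusted p = 0.717). The atrophy ligases Trim63 (301 ± 42.3 against 503 ± 216 CPM, adjusted p = 0.0846), Fbxo32 (446 ± 77.0 against 626 ± 189 CPM, adjusted p = 0.140) and Nedd4 (log2 fold change 0.25 ± 0.12, adjusted p = 0.133) did not pass. Trim63 stood at 253 CPM in denervated WT library 1, within the 252 to 330 CPM of innervated muscle, and at 638 and 617 CPM in the others. Without that library Trim63 and Fbxo32 both rose (adjusted p = 0.00232 and 0.0208). Of 24 chaperones and heat shock genes, 20 rose (20 rose and 1 fell adjusted over the list alone). Hspb8, a small heat shock protein of muscle, rose 5.51-fold (list adjusted p = 2.83e-07; adjusted p = 0.423 with an estimated correlation).

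**Figure D1:**
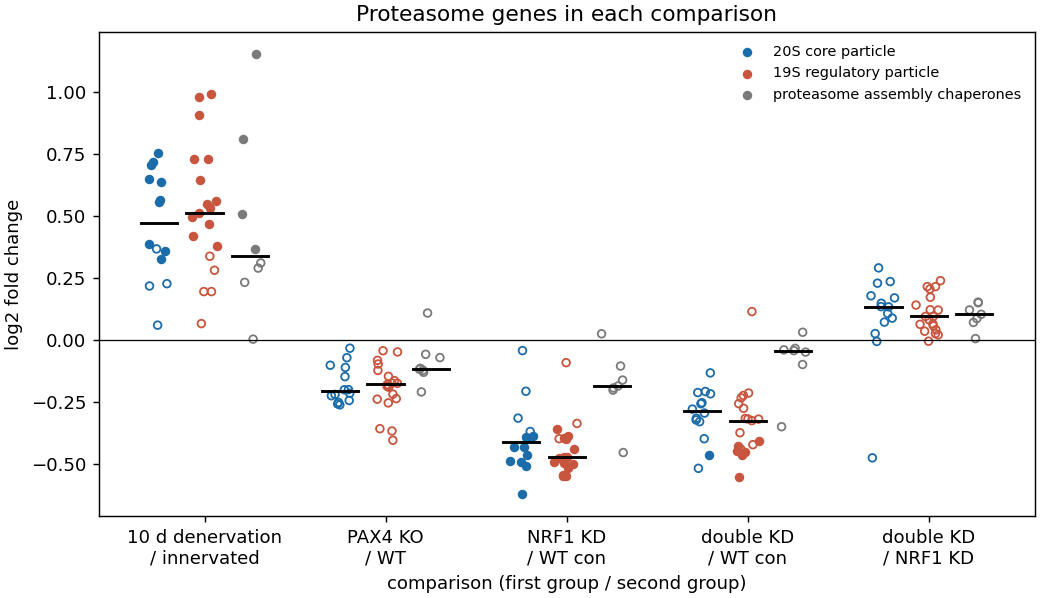
Log2 fold change of each proteasome gene (y axis) in the 5 comparisons (x axis), by part of the complex in colour; filled points passed an adjusted p of 0.05, open points did not, and bars are medians. The genes of the first comparison lie above 0 with 28 of 41 filled, and in NRF1 KD against WT con 26 of 40 are filled and lower.

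Genes known to answer to loss of the nerve changed most by size. Of 24 denervation and neuromuscular junction genes, 17 rose and 2 fell, also when adjusted over the list alone, with a median log2 fold change of 2.07 (list adjusted p = 4.74e-06; adjusted p = 0.423 with an estimated correlation). The fetal and junctional acetylcholine receptor subunits Chrng and Chrnd rose 22.8-fold and 21.1-fold. Cdkn1a, an inhibitor of cell division, rose 7.20-fold, and Ache, the acetylcholinesterase of the junction, fell by 2.09 on the log2 scale. The 5 highest changes under the naming rule were S100a8 (50.6-fold, a neutrophil protein), Krt18 (27.7-fold, a keratin), Chrng, Kcnk5 (21.3-fold, a potassium channel) and Chrnd. Among the lowest were Dhrs7c (-4.69), Ramp1 (-4.01), Mylk2 (-3.66), the myosin light chain kinase of skeletal muscle, and Amd1 (-3.57 on the log2 scale). Innervated library 2 held denervation genes above the other innervated libraries. In it Chrng stood at 16.2 CPM, against 0.192 and 0.104 CPM in the others, and Chrna1 at 110 against 7.81 and 8.43 CPM. Krt18 stood at 28.1 against 0.144 and 0.484 CPM. The folds of Chrng and Krt18 above would be far larger without this library, so the order of the 5 highest changes leans on it.

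Many genes of energy metabolism fell. Of 17 genes of glycolysis and glycogenolysis 15 fell, with a median log2 fold change of -1.52 (adjusted p = 1.80e-10). Of the TCA cycle 18 of 19 fell, with -0.62 (adjusted p = 5.10e-09), and 32 of 71 nuclear genes of the respiratory chain, with -0.45 (adjusted p = 1.80e-10). Adjusted over the list alone, 15, 18 and 37 fell. Targets of alpha-PAL in mitochondrial transcription and import went both ways, with 3 of 17 higher and 3 lower (4 and 3 over the list alone; list adjusted p = 0.624). Gpd1, glycerol-3-phosphate dehydrogenase, fell from 456 ± 61.7 to 72.4 ± 15.8 CPM, and Tpi1, Idh3a and Cs fell by 1.86, 1.20 and 0.91 on the log2 scale. Of 18 mitochondrially encoded genes 13 fell (15 adjusted over the list alone; list adjusted p = 0.000203), mt-Nd2 by 1.49 on the log2 scale. The share of mitochondrial counts was 29.0 ± 0.442% in innervated and 21.0 ± 2.47% in denervated libraries. Cytosolic ribosomal proteins went the other way: 74 of 83 rose (76 adjusted over the list alone), with a median of 0.84 (list adjusted p = 5.62e-20). The muscle form Rpl3l fell by 1.88 on the log2 scale and its relative Rpl3 rose 3.15-fold. Of 13 fast fibre contractile genes 8 fell and 2 rose (9 and 2 adjusted over the list alone; list adjusted p = 0.0101). They were led by Mybpc2, a fast myosin-binding protein (2706 ± 798 to 320.2 ± 93.8 CPM), and by Myh2, a fast oxidative myosin (2.97-fold higher). Each of the 6 lists with an adjusted p under 0.05 in this paragraph had an adjusted p = 0.423 with an estimated correlation. Fry asks only for a common direction of the members. By fry the adjusted p was 0.000684 for glycolysis, 0.00348 for the TCA cycle, 0.0304 for the nuclear respiratory chain and 0.00525 for fast fibre genes.

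**Figure D2:**
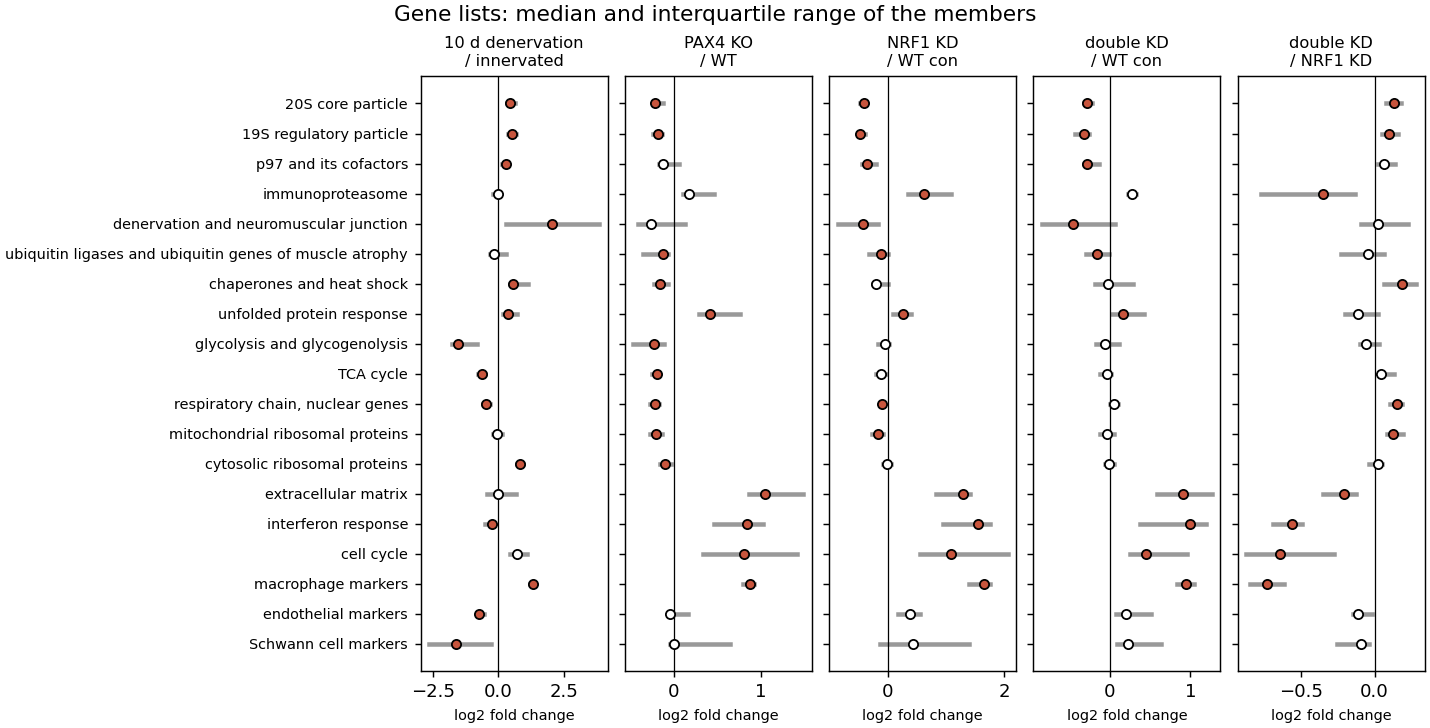
Median log2 fold change of the members of 19 gene lists (x axis; bars are the interquartile range of the members) in each comparison, with filled points for an adjusted camera p under 0.05 at the preset correlation. Glycolysis lies lowest among the metabolic lists in the first panel (-1.52), and macrophage markers lie highest in the third (1.65); no filled point kept its call with an estimated correlation.

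Markers of other cell types moved apart. Of 13 macrophage markers 10 rose (12 adjusted over the list alone; median 1.33, list adjusted p = 0.000219). C1qa, a complement subunit, rose by 1.33 on the log2 scale, to 48.3 ± 10.2 CPM. Of 9 endothelial markers 7 fell (8 over the list alone; median -0.73, list adjusted p = 0.000121). Of 9 Schwann cell markers 5 fell (6 over the list alone; median -1.61, list adjusted p = 0.000679), and of 7 smooth muscle and pericyte markers 6 fell (7 over the list alone; median -0.95, list adjusted p = 0.000679). With an estimated correlation the adjusted p was 0.423 for each of these 4 lists. Of 16146 genes tested in edgeR, 2661 were higher and 2549 lower, and 1155 and 790 when a log2 fold change of at least 1 was asked for. Leaving out innervated library 1 or 3 left 1741 or 1761 genes higher. Leaving out innervated library 2 with denervated WT library 1, a choice made after the data were seen, gave 2617 higher and 2398 lower. In the authors' deposited table for this comparison 5090 genes had an adjusted p under 0.05, and 4071 of them were called here.

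**Figure D3:**
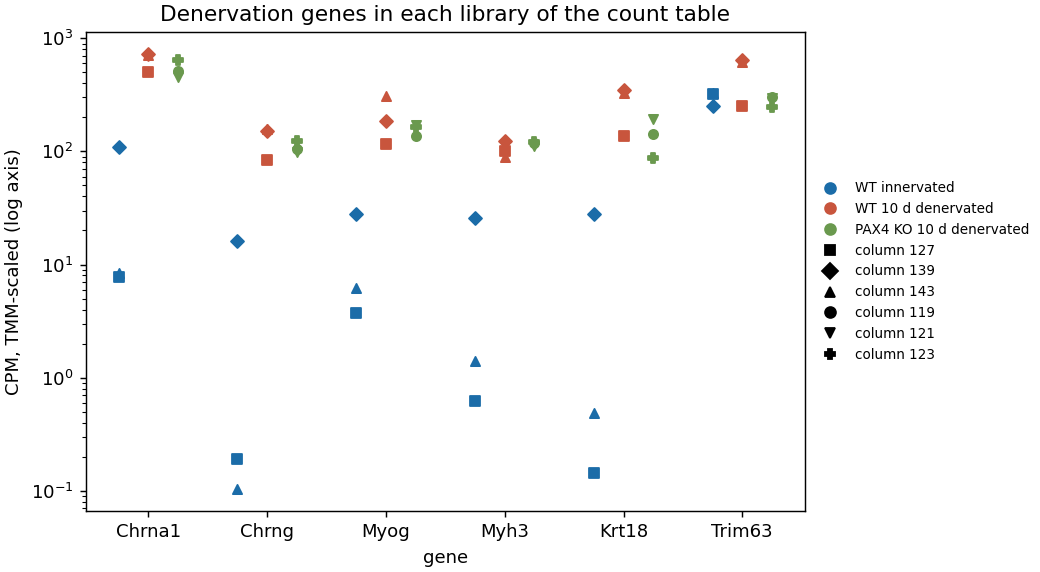
Level of 6 denervation genes in each library of the count table (y axis, CPM scaled by TMM, log axis), coloured by group and shaped by the number in its column name, which rises from library 1 to 3. Innervated library 2 lies between its group and the denervated libraries for Chrna1 (110 CPM), and denervated WT library 1 lies with the PAX4 KO libraries for Trim63 (253 CPM).

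In denervated muscle labelled PAX4 KO, against denervated WT, Esr1 stood apart. Esr1, the estrogen receptor alpha gene (chromosome 10, 4611593 to 5005614, GRCm38), rose 25.8-fold, from 19.5 ± 0.703 to 498 ± 70.9 CPM (SD, n = 3 each, adjusted p = 2.71e-07), and lay at 25.3 to 31.7 CPM in innervated WT muscle. The only other calls were C1qtnf3, a secreted C1q-related protein (1.39 ± 0.278 to 10.6 ± 3.38 CPM, adjusted p = 0.00605), and Ndrg4 (3.43 ± 0.185 to 8.48 ± 0.492 CPM, adjusted p = 0.0304). These 2 lie under the expression minimum of the naming rule and were named after their values were seen. The edgeR test called 3 genes higher and 0 lower of 16146, with 2089 at an unadjusted p under 0.05. DESeq2 called 140 higher and 73 lower, limma-voom 5 and 0, and edgeR without a filter on low counts 348 and 108. In the authors' deposited table of denervated against knockdown muscle, 107 genes were higher and 53 lower at an adjusted p under 0.05, and the 3 called here were among them. For Esr1 that table gave a log2 fold change of 4.63. It gave 6.35 for Dpyd, an enzyme of pyrimidine breakdown, for which the raw counts gave 0.57 ± 0.20 (adjusted p = 0.321). Over 4152 genes with a mean of at least 30 CPM its fold changes and those here had r = 0.971, so the source of the Dpyd value is not known.

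The proteasome genes lay slightly lower in PAX4 KO, without a call. Of 41, 0 passed edgeR's test, over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05. A total of 40 had a negative log2 fold change, with a median of -0.17 and a range of -0.40 for Psmc3 to 0.11 for Psmd5. Camera gave p = 4.78e-08, p = 0.219 with an estimated correlation and p = 0.122 by fry, which looks for a common direction without setting the genes against others. Psmc2 (-0.18 ± 0.11, adjusted p = 0.503), Vcp (-0.18 ± 0.12, adjusted p = 0.526), and Nedd4 (-0.13 ± 0.12, adjusted p = 0.660) did not pass. Nor did Fbxo32 (-0.43 ± 0.22, adjusted p = 0.441) or Trim63 (-0.81 ± 0.29, adjusted p = 0.323). Fast fibre and glycolysis genes lay lower than the proteasome genes, with a joint median of -0.28 over 30 genes, beside macrophage markers at 0.87. Of 13 fast fibre genes 0 passed edgeR over all genes or over the list alone (list adjusted p = 0.00114), and of 17 glycolysis genes 0 and 3 lower (list adjusted p = 0.000692). Each list had an adjusted p = 0.392 with an estimated correlation. Trim63 was uneven within WT: it stood at 253 CPM in denervated WT library 1, at 638 and 617 CPM in the others and at 245 to 306 CPM in the PAX4 KO libraries. The same library held Gadd45a at 255 CPM against 666 and 598 in its group, and the macrophage marker Cd68 at 43.6 against 18.5 and 18.8 CPM. Without it the counts became 16 higher and 10 lower, and 105 and 64 when innervated library 2 was left out as well. Without denervated WT library 2 or 3 only 1 gene was higher, and without PAX4 KO library 1 there were 7 higher and 2 lower.

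Several lists shifted in PAX4 KO by the set test while none of their members passed edgeR's test over all genes. Extracellular matrix genes had a median log2 fold change of 1.04 (adjusted p = 3.97e-12; 16 of 18 higher when adjusted over the list alone). Col5a1, a fibrillar collagen chain, stood at 42.0 ± 11.7 and 124 ± 68.9 CPM (adjusted p = 0.253). Interferon response genes had a median of 0.84 (adjusted p = 1.49e-10; 9 of 14 over the list alone), led by Oasl2 (0.96 ± 0.15, adjusted p = 0.138). Genes of the unfolded protein response had a median of 0.41 (adjusted p = 1.49e-10; 12 of 16 over the list alone), led by the stress pseudokinase gene Trib3 (2.11 ± 0.36, adjusted p = 0.153). Macrophage markers stood at a median of 0.87 (adjusted p = 9.72e-06; 0 of 13 over the list alone). Nuclear genes of the respiratory chain (-0.22, adjusted p = 5.04e-12), mitochondrial ribosomal proteins (-0.20, adjusted p = 2.51e-12) and the TCA cycle (-0.19, adjusted p = 1.87e-06) were lower by camera. Of their members 0 of 71, 0 of 77 and 0 of 19 passed edgeR's test over the list alone. With an estimated correlation no list kept its call: the adjusted p was 0.162 for the interferon list, 0.390 for the unfolded protein response and 0.392 for the others named here. By fry the interferon list (adjusted p = 0.00573) and the unfolded protein response (adjusted p = 0.0337) passed and the other lists did not.

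In the libraries labelled NRF1 KD, against WT con, most proteasome genes were lower. Of 40 measured, 26 fell and 14 did not pass (31 fell adjusted over the list alone), with a median log2 fold change of -0.41 and a range of -0.62 for Psmb3 to 0.03 for Psmd5. In the limma test 0 rose; 39 had a negative fold change. Psmb3 of the core fell from 5366 ± 22.3 (n = 2) to 3502 ± 346 normalised counts (n = 3, adjusted p = 0.0108). Psma7 fell by 0.49 and the 19S subunits Psmc4 and Psmd7 by 0.47 and 0.55 on the log2 scale. Psmc2 fell from 9803 ± 172 to 6979 ± 806 normalised counts (-0.50 ± 0.11, adjusted p = 0.0202). In the core 10 of 14 and in the regulatory particle 16 of 19 genes fell, against 0 of 7 assembly chaperones (0 over the list alone). Of the latter Pomp was nearest to a call (-0.45 ± 0.14, adjusted p = 0.0683). Camera gave p = 4.19e-17, and p = 0.102 with an estimated correlation.

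Around the proteasome, 6 of 13 p97 genes fell (9 fell and 1 rose adjusted over the list alone; list adjusted p = 0.000211). Among them were the cofactors Nsfl1c (-0.44 ± 0.09) and Ufd1 (-0.46 ± 0.10), while Vcp did not pass (-0.37 ± 0.12, adjusted p = 0.0833). Trim63 fell from 21777 ± 4869 to 12654 ± 483 normalised counts (adjusted p = 0.0138), the only call of 16 in its list (1 over the list alone; list adjusted p = 0.0379). Fbxo32 (-0.33 ± 0.12, adjusted p = 0.0991) and Nedd4 (-0.10 ± 0.12, adjusted p = 0.645) did not pass. The interferon-inducible immunoproteasome went up: 3 of 5 genes rose (4 over the list alone; list adjusted p = 0.000934), Psmb8 2.21-fold and Psmb10 1.54-fold. Of 24 denervation and junction genes 11 fell and 2 rose (13 and 3 over the list alone; median -0.42, list adjusted p = 1.02e-05). Musk, the receptor kinase of the junction, stood at 2397 ± 42.2 and 1068 ± 77.2 normalised counts and Gadd45a, a stress gene of atrophy, was lower by a log2 fold change of -1.32 ± 0.14. With an estimated correlation each of these lists had an adjusted p = 0.380. Of 17 targets of alpha-PAL in mitochondrial transcription and import, 0 passed limma over all genes or over the list alone. Their median was -0.11 and the list adjusted p 0.0972, with Polrmt nearest to a call (-0.25 ± 0.11, adjusted p = 0.158).

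Under the naming rule, with its minimum of 8 CPM, the highest changes were Dpyd (107-fold, 148 ± 11.9 to 16073 ± 3385 normalised counts, adjusted p = 4.47e-08) and Esr1 (30.2-fold, adjusted p = 2.20e-09). Next came the chemokine Ccl7 (6.90-fold), the macrophage elastase Mmp12 (6.55-fold) and Cd84 (5.75-fold), a receptor of leukocytes. The lowest were the carboxylesterase Ces2c (-2.31), Fam83d (-2.12), Gdf5 (-1.95), a growth factor of the BMP family, Krt8 (-1.94) and Kcnk5 (-1.65 on the log2 scale). Macrophage markers rose in 12 of 12 cases, also over the list alone, with a median of 1.65 (list adjusted p = 1.73e-10). C1qa rose from 887 ± 140 to 2980 ± 795 normalised counts. Interferon response genes rose in 10 of 14 cases (13 over the list alone; median 1.55, list adjusted p = 4.68e-11), Irf7, a transcription factor of that response, 5.59-fold. Extracellular matrix genes rose in 12 of 18 (15 over the list alone; median 1.29, list adjusted p = 3.64e-09), Timp1 2.66-fold. With an estimated correlation the adjusted p was 0.380 for each of these 3 lists. Of 9 endothelial markers 0 passed limma over all genes or over the list alone (median 0.38, list adjusted p = 0.0651). The same held for 0 of 69 nuclear respiratory chain genes (median -0.09, list adjusted p = 0.0114; adjusted p = 0.768 with an estimated correlation).

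In all, 1184 of 15624 genes were higher and 581 lower in NRF1 KD (limma, adjusted p under 0.05; 759 and 58 with a log2 fold change of at least 1). The counts leaned on single libraries. They were 415 and 156 without WT con library 2, 595 and 292 without NRF1 KD library 2 and 424 and 126 without NRF1 KD library 3. Without WT con library 3, 306 genes were lower. Trim63 lost its call in 2 and Psmc2 in 3 of the 5 fits that left 1 library out. The authors' deposited values gave 1515 genes higher and 844 lower, and 1754 of these were called here.

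In the libraries labelled double KD, against the same WT con libraries, 7 of 40 proteasome genes fell and 33 did not pass (21 fell adjusted over the list alone). They had a median of -0.30, 38 negative values and a range of -0.55 for Psmd2 to 0.12 for Sem1. In limma's test 0 rose, and 26 had an unadjusted p under 0.05. Psmd2, a scaffold of the 19S base, fell from 12858 ± 470 (n = 2) to 8792 ± 894 normalised counts (n = 3, adjusted p = 0.0330). Psmb4 and Psmc4 fell by 0.47 and 0.41 on the log2 scale. Psmc2 was at -0.44 ± 0.11 (adjusted p = 0.0568). Camera gave p = 1.25e-13, and p = 0.138 with an estimated correlation. Both atrophy ligases fell here. Trim63 went from 21777 ± 4869 to 10441 ± 1636 (adjusted p = 0.00952) and Fbxo32 from 17332 ± 1080 to 11366 ± 1101 normalised counts (adjusted p = 0.0240). Nedd4 (0.02 ± 0.12, adjusted p = 0.944) and Vcp (-0.31 ± 0.12, adjusted p = 0.185) did not pass. Of 24 denervation and junction genes 8 fell and 3 rose (13 and 4 over the list alone; list adjusted p = 4.88e-05; adjusted p = 0.580 with an estimated correlation). Myog, a myogenic transcription factor, fell from 10517 ± 191 to 5261 ± 517 normalised counts, and Musk by 0.91 on the log2 scale. Trim63, Myog and Musk kept their calls in every setting tried. Fbxo32 lost its call in 4 settings, 2 of them with 1 library left out, and Psmd2, Psmb4 and Psmc4 in 7 each, 4 of them with 1 library left out.

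Under the naming rule, with its minimum of 8 CPM, Dpyd (108-fold) and Esr1 (30.7-fold) again led the double KD. They were followed by B3galt2 (5.03-fold) and the near-identical heat shock genes Hspa1b (4.88-fold) and Hspa1a (4.55-fold), between which reads can be split in ways the counting does not tell. Fam83d (-2.66), Fam19a5 (-2.34), Kcnk5 (-1.81), Ppp1r27 (-1.76) and Ces2c (-1.58 on the log2 scale) were lowest. Slow fibre contractile genes rose in 2 of 11 cases (2 over the list alone; list adjusted p = 0.00699; adjusted p = 0.626 with an estimated correlation). Casq2, the slow calsequestrin, rose 2.55-fold and Tnni1, the slow troponin I, 2.79-fold. Macrophage markers had a median of 0.95 (2 of 12 rose, 10 over the list alone; list adjusted p = 4.09e-06). Interferon response genes had 0.99 (6 of 14, 10 over the list alone; list adjusted p = 3.47e-06) and extracellular matrix genes 0.90 (3 of 18, 11 over the list alone; list adjusted p = 1.47e-07). Each had an adjusted p = 0.616 with an estimated correlation. By limma 373 of 15624 genes were higher and 265 lower, against 824 and 584 by DESeq2 and 164 and 165 by limma-voom on the recovered reads. Without WT con library 2 the counts were 46 and 40, without double KD library 2 81 and 60, and without double KD library 3 238 genes were higher. The authors' deposited table gave 785 higher and 548 lower, with 636 called in both.

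Calls of NRF1 KD and double KD overlapped, but both used the same WT con libraries. Of 15624 genes, 287 were higher in both (28.3 from independent lists of these sizes) and 202 lower in both (9.85). Simulated groups with no change against the same controls shared 0 calls on average, with r = 0.598 and a covariance of 0.0742 between fold changes across genes, against r = 0.666 and a covariance of 0.241 in the data. The 2 WT con libraries were not split between the comparisons, so part of the excess may come from them. Among the 1765 genes called in NRF1 KD, the median absolute log2 fold change was 0.93 in NRF1 KD and 0.63 in double KD. Being chosen in the first, they are drawn towards larger values there.

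Set directly against NRF1 KD, the double KD showed few calls. Ankrd55, an ankyrin repeat gene, rose 4.65-fold (612 ± 81.3 to 2848 ± 380 normalised counts, n = 3 each, adjusted p = 4.58e-05), Hddc3 4.02-fold (adjusted p = 0.0168) and the methyltransferase gene Hemk1 1.70-fold (adjusted p = 0.0221). Tpbgl (-1.19 ± 0.17), the unconventional myosin Myo7a (-0.88 ± 0.13) and the ribosomal gene Rpl29 (-0.51 ± 0.08) fell. Of these named genes only Ankrd55 kept its call in every setting. The others each lost theirs in 6 to 8 settings, 4 of them with 1 library left out. Esr1 (0.02 ± 0.09, adjusted p = 0.946) and Dpyd (0.02 ± 0.18, adjusted p = 0.980) did not differ past the threshold. Nrf1 (-0.17 ± 0.10, adjusted p = 0.575), Trim63 (-0.29 ± 0.14, adjusted p = 0.476) and Fbxo32 (-0.28 ± 0.11, adjusted p = 0.340) did not pass either. The same held for Psmc2 (0.06 ± 0.10, adjusted p = 0.868), Vcp (0.06 ± 0.11, adjusted p = 0.875) and Nedd4 (0.12 ± 0.11, adjusted p = 0.723). Of 40 proteasome genes 0 passed limma over all genes or over the list alone and 4 had an unadjusted p under 0.05. A total of 37 were positive, with a median of 0.11, camera p = 1.66e-05, p = 0.352 with an estimated correlation and p = 0.217 by fry. With 1 library left out this median ranged from 0.0548 (without double KD library 3) to 0.145 (without NRF1 KD library 2). Macrophage markers had a median of -0.73 (0 of 12 over all genes, 9 lower over the list alone; list adjusted p = 1.86e-08). Interferon response genes lay at -0.56 (0 of 14, 11 lower over the list alone; list adjusted p = 1.67e-08) and nuclear respiratory chain genes at 0.15 (0 of 69 by either adjustment in limma; list adjusted p = 1.67e-08). With an estimated correlation the adjusted p was 0.679, 0.541 and 0.724.

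The counts of this comparison were 12 higher and 9 lower of 15624 by limma, with 1756 genes at an unadjusted p under 0.05. DESeq2 on the recovered reads called 120 and 269, edgeR 11 and 8, and limma-voom 10 and 1, and limma with a pseudocount of 0.1 gave 1 and 0. By the library left out, the counts were 69 and 89 (double KD 1), 1 and 1 (double KD 2), 1 and 0 (double KD 3), 20 and 124 (NRF1 KD 1), 9 and 0 (NRF1 KD 2) and 6 and 1 (NRF1 KD 3).

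Genes that answered to denervation in the first set were then followed in the second, which shares no library with it. The 2541 genes raised by denervation had a median log2 fold change of -0.12 in NRF1 KD (camera at the preset correlation, p = 0.000323; 253 fell and 210 rose) and -0.07 in double KD (p = 0.000526; 135 fell and 84 rose). Estimating the correlation gave p = 0.185 and 0.199, and without WT con library 2 the double KD value was p = 0.0772. The 2382 genes lowered by denervation had medians of 0.03 and 0.06 (p = 0.673 and 0.186 at the preset correlation). Between double KD and NRF1 KD the medians were 0.02 and 0.02 (p = 0.402 and 0.131 at the preset correlation). Of genes called in both sets, 253 rose with denervation and fell in NRF1 KD, where independent lists would share 100, and 210 rose in both, where they would share 202. Genes lowered by denervation were under-represented in both directions: fewer rose in NRF1 KD than the 189 of independent lists, and 51 fell where 94.1 would.

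Whether the change with loss of PAX4 differed with NRF1 KD was tested as a contrast of contrasts over both sets, in which set and kind of PAX4 loss cannot be told from the NRF1 background. In edgeR 1 of 15512 genes, Hemk1 (chromosome 9, 107327084 to 107338350, GRCm38), had a positive difference and 7 a negative one, with 3026 at an unadjusted p under 0.05. A negative difference means a lower log2 fold change for double KD against NRF1 KD than for PAX4 KO against WT, and not a smaller change. Irf7, for example, was at 1.26 in PAX4 KO and at -0.69 in double KD against NRF1 KD, both without a call. Esr1 had the largest difference (-4.64 ± 0.17, adjusted p = 1.49e-10). Interferon genes were among the rest, with -1.95 ± 0.30 for Irf7 (adjusted p = 0.0266) and -1.82 ± 0.31 for Oas2 (adjusted p = 0.0460). The 14 genes of the interferon response had a median difference of -1.35 (list adjusted p = 1.59e-12; adjusted p = 0.0494 with an estimated correlation). Macrophage markers (-1.57, list adjusted p = 1.12e-07), cell cycle genes (-1.41, list adjusted p = 1.34e-05) and extracellular matrix genes (-1.34, list adjusted p = 1.33e-08) moved alongside. These 3 lists had an adjusted p = 0.407 with an estimated correlation. The 40 proteasome genes had a median difference of 0.30 (p = 8.46e-10; p = 0.161 with an estimated correlation). Without denervated WT library 1 the counts were 206 and 498. Leaving out any other library of the 4 groups gave 0 to 46 and 1 to 256.

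**Figure D4:**
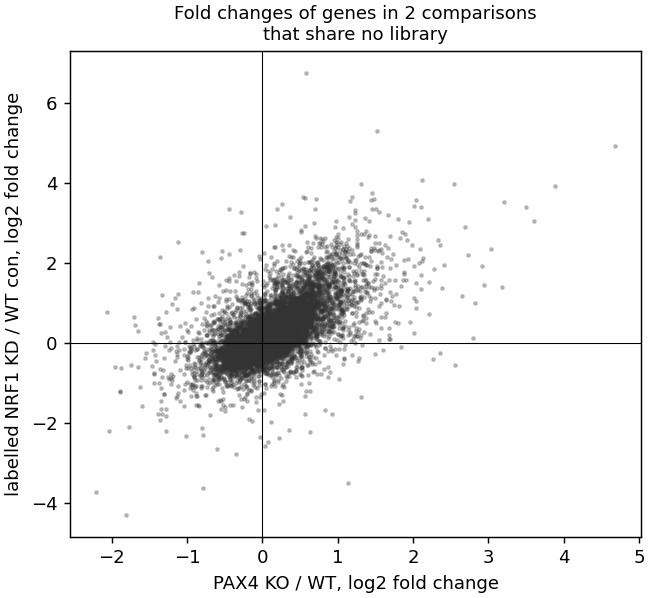
Log2 fold change of 14511 genes in PAX4 KO against WT (x axis) and in NRF1 KD against WT con (y axis), comparisons that share no library; each point is a gene. The points rise together (Pearson r = 0.653 across genes, which are not independent replicates), and Esr1 is the point farthest to the right.

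Fold changes of PAX4 KO and of NRF1 KD, which share no library, went together across 14511 genes (Pearson r = 0.653, Spearman rho = 0.636). So did those of PAX4 KO and double KD (r = 0.547, rho = 0.536). Those of PAX4 KO and double KD against NRF1 KD had r = -0.284 and rho = -0.300. The latter comparison is the double KD change less the NRF1 KD change. The negative sign thus follows from the covariances with PAX4 KO, 0.1154 for double KD and 0.1648 for NRF1 KD, and is no separate observation. All these correlations describe genes, which are not independent replicates, and 7 such pairs of comparisons were computed. PAX4 KO and NRF1 KD also shared higher macrophage markers (medians of 0.87 and 1.65) and higher Esr1 (4.69 and 4.92 on the log2 scale). Endothelial markers had medians of -0.04 and 0.379. What made the fold changes go together was not tested, so the correlation does not show shared targets of PAX4 and NRF1. Denervation and PAX4 KO, which share the denervated WT libraries with opposite sign, had r = -0.003 and a covariance of -0.0012. Groups simulated without any change, also none with denervation, gave r = -0.485 and a covariance of -0.0562. Denervation called 5210 genes in the data, so that simulated r is no reference for them. Of the calls of denervation and PAX4 KO only Esr1 was shared, lower with denervation (log2 fold change -0.56) and higher in PAX4 KO.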

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

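The differences below come from a planned contrast of contrasts, and the tests of each explanation were chosen after results had been seen; only the splits of libraries were planned. The change labelled as loss of PAX4 differed between libraries with and without NRF1 KD for 8 genes (edgeR, adjusted p under 0.05). Set and kind of PAX4 loss cannot be told from the NRF1 background. Only Esr1 (in PAX4 KO) and Hemk1 (in double KD against NRF1 KD) were called in a comparison that makes up the difference. With 1 library left out, 0 to 206 genes had a positive and 1 to 498 a negative difference. On the log2 scale the difference was -4.64 for Esr1, which rose with PAX4 KO alone and did not differ between double KD and NRF1 KD. Interferon-related genes followed: Ifit1bl1 (-3.815), Irf7 (-1.948) and Oas2 (-1.815). Ifit1bl1 lay near the floor in the first set, at 0.195 CPM in denervated WT and 0.519 CPM in PAX4 KO. The 14 genes of the interferon response had a median difference of -1.352. Macrophage markers moved by more, with a median of -1.57, so these differences came beside a shift in cell markers. Bst1, a surface enzyme of myeloid cells, differed by -2.925, with means of only 0.529 CPM in denervated WT and 1.48 CPM in PAX4 KO. Aldh18a1, an enzyme of proline synthesis, and Slc7a1, a carrier of cationic amino acids, differed by -1.526 and -1.499. Hemk1, a methyltransferase gene, was alone in the other direction, at 0.9966.

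Esr1 was higher in all 3 groups labelled KO or KD. Loss of PAX4 alone did not account for it, since Esr1 was higher by 4.917 in NRF1 KD against WT con, and loss of NRF1 alone did not either, since it was higher by 4.688 in PAX4 KO. A transgene that carries part of Esr1, whose reads could be counted under the gene, remained open. Esr1 in double KD lay 0.02296 from NRF1 KD, a value such a shared transgene would give, but so would any effect common to these mice. The labels name no recombinase, and every altered library differs from WT in genotype, so the data here cannot separate these readings.

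Proteasome genes were lower beside higher macrophage markers in NRF1 KD. A smaller share of muscle fibre RNA was tested with fast fibre and glycolysis genes, whose median of -0.1228 lay above the 75th percentile of the proteasome genes (-0.331). These genes thus fell by less than the proteasome genes. Both lists also had negative medians with denervation (-0.953 and -1.52), so they are no neutral gauge of fibre RNA. Endothelial markers, which dilution would raise with the macrophage markers, had a median of 0.379 with no member called. Other marker lists, looked at after their values were seen, were mixed. The fibroblast markers Ly6a and Dpt rose by 0.75 and 0.90 and the pericyte marker Cspg4 by 0.58 on the log2 scale, each called. Adipocyte and tendon markers had no call, with Fabp4 (0.31 ± 0.11) and Scx (-0.58 ± 0.22) nearest. Whether dilution was the main source stays open. With TMM in place of the authors' size factors the proteasome median moved from -0.4137 to -0.3774, and lay -0.4138 from that of all genes. Size factors shift all genes of a library nearly alike, so that distance was bound to hold and cannot test scaling. Leaving out either WT con library kept the median at -0.3685 or lower, which argued against 1 control library standing apart.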

How the results depend on the processing

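The fit without innervated library 2 and denervated WT library 1, the tools on recovered reads, TMM and the deposited log2 values for the second set, and the block by column number were added after seeing the data; the other settings were planned. No named gene or list that had been called changed direction in a setting; other called genes were not followed. The share of calls that were higher did turn in double KD against NRF1 KD, from 57.1% to 30.9% with DESeq2 and 13.9% without NRF1 KD library 1. Not run were all settings for 14 d muscle and for 10 d against 14 d, the block for the contrast of contrasts, and the fit without a filter for the second set, whose table had been filtered. The cause of the shifts below was not tested.

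With an estimated inter-gene correlation the proteasome p was 0.1492 for denervation, 0.2187 for PAX4 KO, 0.1015 for NRF1 KD, 0.1378 for double KD and 0.3523 for double KD against NRF1 KD. In each of these comparisons 0 lists remained higher and 0 lower. Denervation-raised genes had p = 0.1851 in NRF1 KD and 0.1987 in double KD with that correlation. With fry in place of camera the proteasome p was 0.122 in PAX4 KO and 0.2174 in double KD against NRF1 KD. Lists higher and lower were then 2 and 0 in PAX4 KO, 0 and 2 in double KD and 0 and 0 in double KD against NRF1 KD. In NRF1 KD 5 were higher, and 6 of the 18 lists called there by camera lost their call. For denervation 2 of 24 called lists lost their call with fry and 1 was gained.

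With a log2 fold change of at least 1, genes higher and lower were 1155 and 790 for denervation, 759 and 58 for NRF1 KD and 209 and 45 for double KD. In PAX4 KO the DESeq2 Wald test gave 140 and 73, limma-voom 5 higher, no filter on low counts 348 and 108, and leaving out innervated library 2 and denervated WT library 1 together 105 and 64. In double KD, only the 2 groups compared gave 146 and 85, the deposited log2 values 241 higher, DESeq2 on recovered reads 824 and 584 and limma-voom 164 and 165. In double KD against NRF1 KD, a pseudocount of 0.1 gave 1 and 0, at least 5 CPM 1 and 0, only the 2 groups compared 45 and 34, DESeq2 120 and 269, and limma-voom 1 lower. Genes lowered by denervation had p = 0.0333 at the preset correlation in double KD when the set was defined without innervated library 2 and denervated WT library 1. The 200 genes with the smallest adjusted p among those raised had p = 0.00768 at the preset correlation in double KD against NRF1 KD. At least 5 CPM gave 2 genes with a positive difference in the contrast of contrasts.

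The labels do not say whether libraries of the same number belong together, and no pairing was assumed. Correlations of residual values between libraries of the same number were 0.184, 0.0855 and 0.354 for denervated and innervated WT, each the highest for its denervated library, so pairing in that set stays open. They were 0.0924 and 0.297 for NRF1 KD and WT con, -0.0821 and -0.374 for double KD and WT con, and -0.341, -0.109 and -0.387 for double KD and NRF1 KD. With a replicate block, 984 genes and 14 lists were lower in NRF1 KD. The block gave 105 genes higher and 60 lower in double KD, and 24 higher in double KD against NRF1 KD. WT con library 1 had no column, so against WT con the block in effect dropped library 1 of NRF1 KD and of double KD. The proteasome medians with the block, -0.4475 in NRF1 KD and -0.262 in double KD, equalled those without that library. With the block by column number, 2538 genes were higher and 2496 lower by denervation. No paired analysis was possible for PAX4 KO against WT because their columns share no number.

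Leaving out each library in turn gave these ranges, lowest to highest. Genes higher by denervation numbered 1741 to 2692. In PAX4 KO 1 to 16 were higher and 0 to 10 lower, in NRF1 KD 415 to 1190 and 126 to 421, in double KD 46 to 474 and 40 to 248, and in double KD against NRF1 KD 1 to 69 and 0 to 124. Lists lower in double KD numbered 7 to 11 and lists higher in double KD against NRF1 KD 5 to 13. For denervation-raised genes the camera p ranged from 1.21e-05 to 0.0772 in double KD and from 0.0445 to 0.875 against NRF1 KD; for lowered genes from 0.0216 to 0.907 and from 0.0207 to 0.476. In the contrast of contrasts 0 to 206 genes had a positive and 1 to 498 a negative difference.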

Other observations

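Denervation changed the fibre type genes in detail. These genes and those of the next paragraph were chosen after their values were seen. Myh4, the fastest myosin heavy chain, fell from 23752 ± 9841 to 6794 ± 721 CPM and Myh1 from 7338 ± 1660 to 3084 ± 723 CPM (edgeR adjusted p = 0.00523 and 0.00223). Runx1, a transcription factor of denervated muscle, rose 14.5-fold, and Ncam1, an adhesion protein of immature and denervated fibres, 7.57-fold. Innervated library 2 held Runx1 at 14.4 CPM, against 1.965 and 1.83 in the others, and Ncam1 at 15.96 against 2.54 and 3.45. Both folds would be larger without it. Map1lc3a, a coat protein of autophagosomes, rose 3.89-fold. The stress factors split: Xbp1 rose 1.58-fold while Atf4 fell by 0.57 on the log2 scale.

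In NRF1 KD the metallothioneins Mt1 and Mt2, which bind metal ions, rose 2.55-fold and 2.46-fold (limma adjusted p = 0.0289 and 0.0216). The partners S100a8 and S100a9, which form a neutrophil protein together, went opposite ways: S100a8 fell from 2389 ± 604 to 798 ± 151 normalised counts and S100a9 rose from 42.01 ± 11.4 to 239 ± 83.0. Some single genes, picked after their values were seen and not tested as a group, differed by near presence and absence. Hmga1b stood at 58.0 normalised counts in double KD, 0.599 in NRF1 KD and 0 in WT con, Gbp2b at 95.2, 2.07 and 2.48, and Ifi44l at 29.4, 0.599 and 0.485. Pdzd3 did the reverse, at 0.726, 31.1 and 32.7.

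Innervated library 2 held denervation genes above the other innervated libraries. The test was written after this was seen. Over 159 genes raised by denervation its median lay 15.28% of the way to the denervated level, and over 99 lowered genes 38.1%. The difference of 22.77 points argued against a plain mixture with RNA like that of these denervated libraries, and 15.28% argued against a denervated library with the wrong label. No biological cause was tested.

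The libraries of each comparison with 3 against 3 were also regrouped in the 10 ways possible, a test planned beforehand. Denervation called 5210 genes and the highest other grouping 0, PAX4 KO 3 and 1, and double KD against NRF1 KD 21 and 0. In each case 1 of 10 groupings, the real one, called as many genes, and 10 splits are too few for a share under 0.05.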
